A study of Mus musculus with 31 samples.

How the data were processed

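The series measured allele-specific RNA in placentas and yolk sacs of F1 hybrids between 2 mouse strains, C57BL/6 (B6) and Mus musculus castaneus (Cast). Per the labels' protocols, mRNA was heat sheared, reverse transcribed from an oligo-dT primer and sequenced on an Illumina Genome Analyzer II in the 3SEQ protocol, which reads the 3′ ends of transcripts. The submitters' processing notes name the mm9 build and BWA, with no version of the latter. Caller, polymorphism source, filters and read duplicates are not given in the sources used here.

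The deposited file of each of the 30 placenta and yolk sac libraries lists single-base positions with a strand and a fraction from 0 to 1. From the values, this fraction is the share of reads with the B6 allele: it is near 1 on the X chromosome of offspring of B6 mothers and near 0 on that of offspring of Cast mothers. This orientation was taken from X and is not in the labels, so a maternal share above 50% on X is built into it, while the autosomes were not used to set it. In 6 deposited files (B1-2 and the 5 libraries of litter C1) the end coordinate and the fraction were written without a separator, and they were parsed as start plus 1 followed by the fraction. The decidua file, as deposited, holds a score per position in place of a fraction, from 0.01189 to 1000, and 100% of its values were whole multiples of the lowest within a tolerance of 0.01 of a step. The score was used only to rank positions within that library.

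The coverage behind each fraction is not given, so the depth per site is unknown and no interval for counting error was computed. The number of sites per library stands in for depth. Between 76.7% and 93.1% of the sites of a library were at 0 or 1. Repeated lines carried the same value and were counted once, both strands of a site were averaged, and chromosomes 1 to 19 and X were used. Libraries of a group were compared before averaging: 2 libraries shared at most 64.1% of the sites of the smaller, with the same fraction at up to 68.2% of shared sites, over 132 pairs, so none was treated as a copy of another.

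Groups and litters were taken from the labels: 12 E11.5 placentas of B6 mothers in 3 litters, 11 E11.5 placentas of Cast mothers in 2 litters, 5 E17.5 placentas of B6 mothers, 2 E11.5 yolk sacs of Cast mothers and 1 E11.5 decidua. Placentas of a litter share a mother, litter is nested in cross, and the litters of the E17.5 placentas and yolk sacs were not given, so p-values over placentas can be too small. The maternal percent is the B6 share for B6 mothers and its complement for Cast mothers, as a plain mean over sites. Means per library were compared with two-sided permutation tests (exact, or 100000 resamples where both groups hold 10 or more libraries), and the 19 tests of shares were adjusted together by the Benjamini-Hochberg method.

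Sites within 100 bases of the next were joined into regions over all libraries. For each region with a value in at least 6 placentas of each cross, the B6 share was fitted with limma 3.58.1 (R 4.3.3), weighted by the number of sites read. A parent-of-origin call needed an adjusted p under 0.05 (Benjamini-Hochberg) for the difference between crosses and the same parent above 50% in both. A strain call tested whether the mean of the crosses differed from 50%. The stage fit needed values in at least 3 E17.5 placentas and 6 E11.5 placentas of B6 mothers, and the yolk sac fit values in both yolk sacs and 6 placentas of Cast mothers. As most calls were maternal, a test of the paternal direction alone was added, with its own adjustment, and its regions were joined into loci within 100000 bases. On simulated data made from the 140306 regions of the parent-of-origin fit, differences of 30, 60 and 90 percentage points, given to 200 regions each, were recovered in 3%, 19.5% and 69.5% of regions, and 4.17% of calls were false. The simulation kept unchanged regions in a band around an even share and drew a single read per site. It held no litter effect and no maternal excess of whole libraries, so its false share does not give the error of the real calls. The stage and yolk sac fits were not simulated.

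The plan written before the data were examined expected counts. As the values are fractions, the count tests, the comparisons of total expression between crosses, stages and tissues, the tests of marker lists and the alternatives that belong to them were not run, and limma on the fraction took the place of the planned allele test. The named regions follow the planned rule as far as it fits: the 10 calls with the largest effect in each direction per comparison, ties broken by the smallest p. No annotation of mm9 was used here, so positions carry no gene names and no exon or UTR. Of the planned lists, those of imprinted genes were used by name and chromosome only, through the RefSeq table of assembly GRCm38.p6. All 34 maternally expressed and 33 of the 35 paternally expressed names were matched. Other minimums, joins, scales, weights, thinned libraries, left-out litters and left-out libraries were tried as alternatives. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.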

Results

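To ask whether transcripts of the mouse placenta come from the maternal or the paternal allele, 3′-end RNA libraries of reciprocal F1 hybrids between the strains B6 and Cast were compared. The collection held 12 placentas of B6 mothers and 11 of Cast mothers at E11.5 (midgestation, in embryonic days), 5 placentas of B6 mothers at E17.5 (near term), 2 yolk sacs of Cast mothers at E11.5, and 1 decidua of E11.5, the maternal tissue that borders the placenta. An allele preferred because of its parent changes strain between the reciprocal crosses, and an allele preferred because of its strain does not. The libraries listed 220443 to 1035136 sites in the placentas of B6 mothers and 247802 to 1881752 in those of Cast mothers. The E17.5 placentas were smaller, with 30749 to 214385 sites. The yolk sacs listed 231369 and 241629 sites and the decidua 802382. The reads behind a site are unknown, and most sites carried a share of 0 or 1.

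Averaged over the listed autosomal sites, the share of E11.5 placentas was mostly maternal in both crosses, but near even at the sites that every placenta listed (given below). The mean maternal share over all sites, each counted alike because its coverage is unknown, was 74.8% ± 7.36 (SD, n = 12) with B6 mothers and 71.7% ± 10.9 (SD, n = 11) with Cast mothers. It exceeded 50% in 12 of 12 and in 11 of 11 placentas. On single autosomes it ran from 71.6% ± 6.99 on chromosome 11 to 77.4% ± 7.04 on chromosome 3 with B6 mothers (SD, n = 12), and the same chromosomes were lowest and highest with Cast mothers, at 68.9% ± 10.8 and 73.9% ± 10.7 (SD, n = 11). The excess over 50% gave p = 0.000488 and p = 0.000977 in exact two-sided sign-flip permutation tests, the smallest these designs allow (adjusted p = 0.00155 and 0.00169 over 19 tests).

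**Figure D1:**
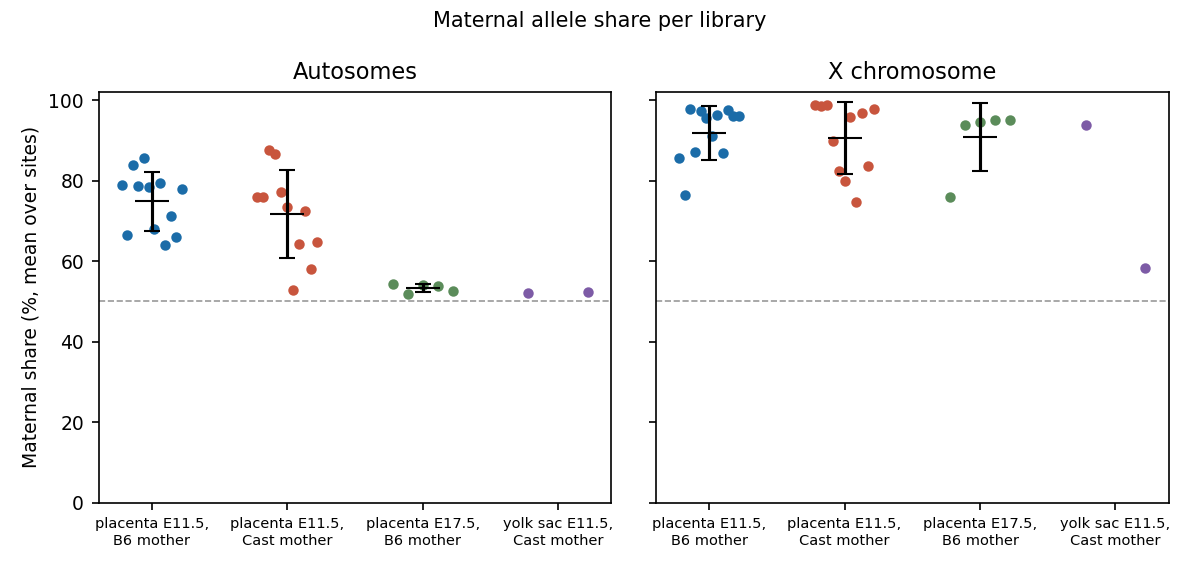
Maternal allele share per library as a percent (mean over sites), on autosomes (left) and X (right). Points are libraries, black bars are the mean ± SD of groups with more than 2 libraries, and the dashed line is an even share. All 23 E11.5 placentas lie above 50% on autosomes, while the E17.5 placentas lie at 51.9% to 54.4% and the yolk sacs at 52.1% and 52.3%.

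The crosses did not differ by more than the spread between placentas when all were pooled: the B6-mother mean was 3.15 percentage points higher (two-sided permutation test, p = 0.42, adjusted p = 0.469). It turned to -5.79 points without litter C2 (permutation p = 0.145) and was 1.75 points at the sites listed in all 23 placentas (permutation p = 0.0178). Within the files of regular layout, which hold litter C2 as the only Cast-mother litter, the means were 74.5% (n = 11) and 64.3% (n = 6), a difference of 10.2 points (exact permutation test, p = 0.0228). The other layout held 1 placenta of a B6 mother against 5 of Cast mothers, too few for a value. Litter means ran from 64.3% in C2 (n = 6) to 80.6% in C1 (n = 5), both of Cast mothers, and the 3 litter means of B6 mothers against the 2 of Cast mothers gave p = 1 in an exact permutation test that can reach 0.2.

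The maternal excess was smallest at the sites that every placenta listed. At the 18950 autosomal sites listed in all 23 placentas the maternal share was 53.9% ± 2.195 (SD, n = 12) with B6 mothers and 52.2% ± 0.994 (SD, n = 11) with Cast mothers, still above 50% in every placenta. At the 290360 sites listed in 10 to 14 placentas it was 79.6% ± 6.61 (SD, n = 12) and 74.0% ± 9.73 (SD, n = 11). The difference between these classes was 25.6 points with B6 mothers and 21.8 points with Cast mothers, present in 12 of 12 and 11 of 11 placentas (exact sign-flip permutation tests, p = 0.000488 and 0.000977, the smallest possible, adjusted p = 0.00155 and 0.00169). Among the 12 placentas of B6 mothers the share also followed the number of sites a library listed, with Pearson's r of 0.649 (permutation p = 0.0155) and Spearman's rho of 0.706 (permutation p = 0.0122), and r was 0.731 without the 2 libraries farthest from the median. The Cast-mother litters did not overlap in their number of sites, so no pooled value is given. In C2 alone (n = 6) r was 0.679 (exact permutation p = 0.125) and rho 0.771 (exact permutation p = 0.103), and r was 0.917 without the 2 farthest libraries. In the 11 B6-mother placentas of regular layout r was 0.781 and rho 0.736 (permutation p = 0.00616 and 0.0133, adjusted over 2 sets 0.0123 and 0.0267).

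**Figure D2:**
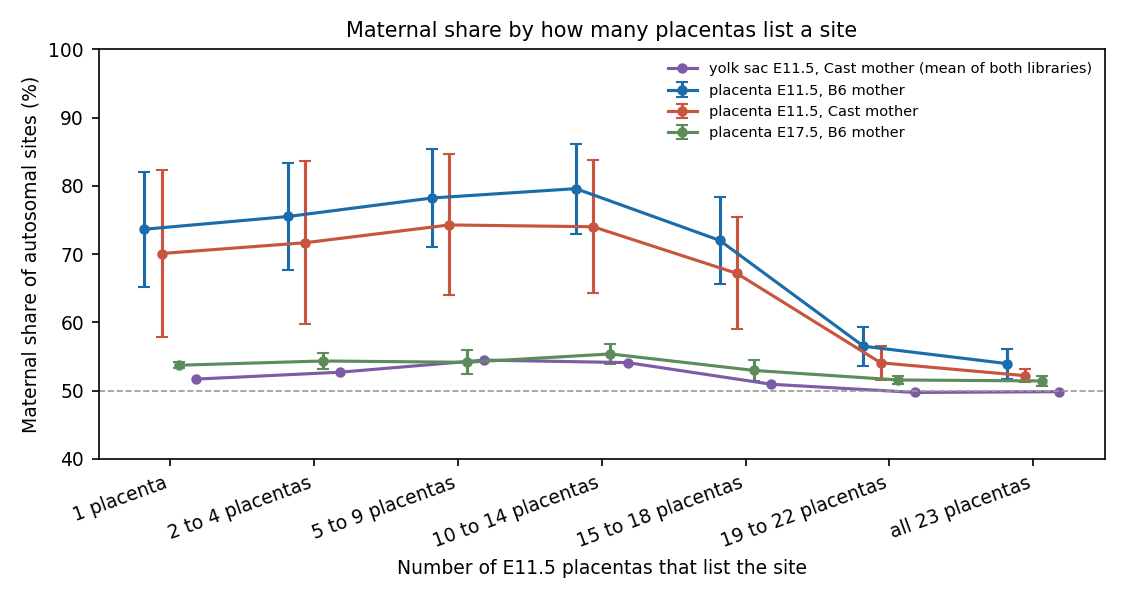
Mean maternal share of autosomal sites (percent, vertical axis) by the number of E11.5 placentas that list a site (horizontal axis), per group. Bars are the SD between libraries, and the dashed line is an even share. Both E11.5 placenta groups lie above 70% at sites of up to 14 placentas and reach 53.9% and 52.2% at sites of all 23.

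Averaged over its listed sites, the X chromosome was read mostly from the maternal allele. Its maternal share was 91.9% ± 6.69 (SD, n = 12) with B6 mothers, 90.6% ± 8.94 (SD, n = 11) with Cast mothers and 90.8% ± 8.38 (SD, n = 5) at E17.5. In extraembryonic tissues of female mice the paternal X is the inactive one, and males carry a maternal X only. X exceeded the autosomes by 17.1 points with B6 mothers and 18.9 points with Cast mothers, in 12 of 12 and 11 of 11 placentas (exact sign-flip permutation tests, p = 0.000488 and 0.000977, the smallest possible, adjusted p = 0.00155 and 0.00169). The gap depended on the sites and was wider at those listed in all 23 placentas. There X was 88.3% ± 7.31 (SD, n = 12) and 94.1% ± 2.34 (SD, n = 11) maternal, against 53.9% and 52.2% on autosomes. At E17.5 the excess was 37.5 points in 5 of 5 placentas, where the exact test cannot go below its p = 0.0625. The orientation of the shares was set from X, so the direction on X is not independent, and only its size is.

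X held a short interval with the opposite direction. Of the 2628 windows of 10000 bases with at least 20 site values per cross, 4 were over 50% paternal in both crosses, against medians of 6.02% and 8.08% paternal. Adjacent windows among them span chrX 100,650,001 to 100,680,000 (mm9), where the window from 100,660,001 to 100,670,000 was 74.9% paternal over 84 site values with B6 mothers and 67.3% over 108 with Cast mothers. The remaining window was 166,420,001 to 166,430,000, at 50.3% and 52.4% paternal. X carries Xist, the non-coding RNA transcribed from the inactive X, but no annotation of mm9 was used here to place it. These windows were picked for their shares and were not tested.

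**Figure D3:**
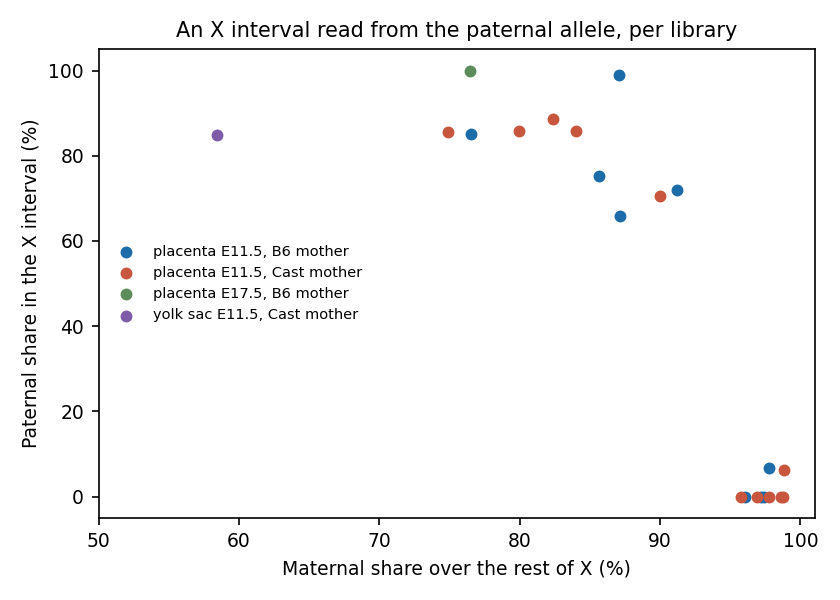
Paternal share of the interval chrX 100,650,001 to 100,680,000 (percent, vertical axis) against the maternal share of the rest of X (percent, horizontal axis). Each point is 1 of the 22 libraries with at least 3 sites in the interval, coloured by group; the points lie either at 65.9% to 100% paternal with up to 91.2% maternal over the rest of X, or at 0% to 6.67% with 95.8% to 98.8%.

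Regions of joined sites showed the same direction. Of 140306 regions tested between the crosses, 82685 had a parent-of-origin bias, 82266 maternal and 419 paternal (limma, Benjamini-Hochberg adjusted p under 0.05). On X 3725 of 3858 regions were maternal and 0 paternal by limma, with 5 at an unadjusted p under 0.05 for the paternal direction, and on autosomes 78541 of 136448 were maternal. Among the 12948 autosomal regions read in all 23 placentas the calls were fewer, 1299 maternal and 92 paternal. These used the adjustment over all regions, which the many maternal calls make lenient. Of the 92, 39 also passed the test of the paternal direction alone, and a fit of such regions alone gave fewer calls (given below). The count over all regions changed with litters: without B1 it was 12240 of 50549, without C1 17835 of 79071, and without C2 it rose to 125441 of 191892.

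The 10 strongest maternal regions by the named rule were read from the maternal allele in every placenta with a value, at 100% ± 0 in both crosses. The first was 92,584,950 to 92,585,123 on chromosome 16 (6 sites, n = 12 and 11, adjusted p = 9.54e-28), with a neighbour at 92,584,785 to 92,584,820 that was 100% maternal as well. The others lay on chromosome 2 at 150,404,191 to 150,404,306, on chromosome 5 at 36,010,762 to 36,010,946, on chromosome 7 at 50,904,016 to 50,904,131, and at single sites on chromosome 14 (56,796,960), chromosome 17 (25,885,710) and chromosome 4 (138,438,624). On X they were 162,828,939 to 162,828,949 and 66,022,239 to 66,022,441. Their adjusted p ran up to 4.39e-20. The 8 autosomal regions carried decidua scores from 0.345 to 9.49, so all 8 were also read in the decidua. That alone does not set them apart. Of the 11557 autosomal regions read in every placenta of both crosses without a parent-of-origin call, only 127 had no decidua signal. The median score of those 11557 was 0.321, below the scores of all 8, though not all of the 8 were read in every placenta.

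Few regions had a paternal bias, taken as a share under 50% maternal in both crosses. Relative to the mean of each library, a scale on which a region only has to lie below that mean, 17192 of 47180 calls were paternal. When the share itself was used and the paternal direction alone was tested, 108 regions passed (limma, Benjamini-Hochberg), and they formed 32 loci on 12 chromosomes, 20 of them with 2 or more regions. The largest was chr7 6,656,662 to 6,722,621 with 18 regions, whose mean maternal share was 13.2% with B6 mothers and 1.85% with Cast mothers. Next came chr6 4,624,380 to 4,710,351 with 14 regions at 3.45% and 4.27% maternal, and chr2 10,491,727 to 10,516,578 with 9 regions at 13.999% and 4.81%. The locus at chr17 12,955,707 to 13,052,789 had 8 regions at 6.34% and 4.75%, chr15 96,990,521 to 96,997,676 had 6 at 6.06% and 13.1%, and chr7 149,838,037 to 149,855,980 had 5 at 3.60% and 3.74%. On chromosome 12, neighbouring loci at 110,691,877 to 110,698,537 and 110,827,475 to 110,839,215 held 3 regions each, at 7.03% and 3.24% and at 5.43% and 8.15% maternal. The two-sided test of all regions called 419; its adjustment is shared with the maternal calls.

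As background, the fixed list of known paternally expressed genes places Peg3, Usp29 and Igf2 on chromosome 7, Peg10, Sgce and Mest on chromosome 6, Sfmbt2 on chromosome 2, Dlk1 and Rtl1 on chromosome 12, Slc38a4 and Peg13 on chromosome 15, and Airn on chromosome 17. Igf2 encodes a fetal growth factor, and Peg10 and Rtl1 derive from retrotransposons and are needed for placental growth. The 12 chromosomes that carry a gene of this list held 30 of the 32 loci and 63.8% of the 136448 autosomal regions tested. This compares chromosomes, not positions, and was not tested.

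The paternal regions named by the rule were read mostly from the paternal allele in the placentas with a value, as few as 6 of the 12 of B6 mothers at chr6 4,703,979. The single site chr6 4,707,924 was 0% ± 0 maternal in both crosses (SD, n = 11 and 10, limma adjusted p = 8.64e-19). The sites chr7 149,855,980, chr10 12,848,361 and chr6 4,703,979 were at 0% as well. At chr6 4,709,371 to 4,709,392 the maternal share was 0.0868% ± 0.301 (SD, n = 12) with B6 mothers and 0% ± 0 (SD, n = 11) with Cast mothers. The other named regions, chr7 6,662,661, chr2 174,092,537 to 174,092,797, chr17 13,015,510, chr12 110,827,475 and chr6 4,706,799, had maternal shares of up to 1.68%. Decidua scores of the 10 regions reached 0.987.

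Most of the paternal regions were also under 50% maternal outside the placentas that defined them. Of the 93 paternal regions with a value at E17.5, 87 were under 50% maternal, with a median of 0%. Of the 91 with a value in yolk sac, 79 were, with a median of 2.82%. Regions of a locus are not independent, and 96 of the 108 lay in the 20 loci of several regions. Of the 12 single-region loci, those at chr2, chr3, chr4 and chr11 116,543,217 were at 50% to 100% maternal at E17.5. In yolk sac those at chr8 and at chr11 51,053,042, 97,190,406 and 116,543,217 were at 84.1% to 100%. The other single-region loci with a value were under 50% in each group. At the chr6 locus of 14 regions the mean maternal share was 1.81% at E17.5 and 10.2% in yolk sac, and at the largest chr7 locus it was 4.41% and 10.7%. Only 1 cross is present in either group, so strain and parent cannot be told apart there.

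A strain bias was called in 16557 of the 140306 regions, with the B6 allele higher in 9884 (limma, Benjamini-Hochberg). Of the 16557, the same allele was higher in both crosses in 8863 (B6) and 6531 (Cast). Over all regions the mean of the crosses was 52.1% B6. At regions read in all 23 placentas it was 50.9% on autosomes and 48.3% on X. This mean also moves with any difference in maternal excess between the crosses and does not measure a strain preference alone. The mean autosomal B6 share was 74.8% with B6 mothers and 28.3% with Cast mothers. The strongest B6 examples were chr14 69,981,983 to 69,982,296, chr14 69,966,963 to 69,967,077 and chr9 65,913,043 to 65,913,113, at 100% B6 in both crosses. The strongest Cast examples were chr9 57,233,509 to 57,233,689, chr10 82,112,962 to 82,113,043 and chr5 22,059,943 to 22,060,041, at 0% B6 in both. Alignment to a B6 genome would raise the B6 share, and its size was not measured apart.

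At E17.5 the mean autosomal share was close to even. It was 53.3% ± 1.06 (SD, n = 5) against 74.8% ± 7.36 (SD, n = 12) at E11.5 with mothers of the same strain, a change of -21.5 points (exact permutation test, p = 0.000323, the smallest possible, adjusted p = 0.00155). The E17.5 share was above 50% in 5 of 5 placentas, where the exact test cannot go below its p = 0.0625. X did not differ by more than the spread (difference -1.08 points, exact permutation test, p = 0.776, adjusted p = 0.776). At the sites listed in all 23 E11.5 placentas the change was -2.53 points. Every E17.5 library listed fewer sites than every E11.5 library, so stage and number of sites are confounded.

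Of 24772 regions tested between the stages, 347 differed, 291 with a lower and 56 with a higher maternal share at E17.5 (limma, Benjamini-Hochberg). This fit held B6 mothers only, so the maternal share is also the B6 share. Parent and strain cannot be told apart in these changes. The median difference of all regions was -3.00 points. None of 455 X regions passed, with 4 at an unadjusted p under 0.05. The 10 named falls went from 100% to 0% maternal, and rested on 3 E17.5 placentas each: chr9 20,349,783 to 20,349,807 (adjusted p = 1.47e-09), chr8 32,739,315 to 32,739,577, chr17 24,554,322 to 24,554,357, chr3 90,164,846, chr8 73,801,786, chr6 115,439,433 to 115,439,486, chr12 29,134,119, chr12 57,294,233, chr14 120,793,426 and chr19 48,159,716. They had values in 6 to 9 of the E11.5 placentas, with an SD of 0 in both groups. With the reads per site unknown, their p-values do not measure counting error and do not show a complete switch. The 10 named rises began with chr6 35,320,530 to 35,320,830, from 3.54% ± 5.86 (SD, n = 11) to 85.7% ± 50 (SD, n = 4; the mean is weighted by sites and the SD is not), and chr12 32,610,626, from 17.9% ± 21.8 (SD, n = 11) to 100% ± 0 (SD, n = 3). The others were chr12 59,367,849 to 59,368,060, chr10 79,440,989, chr2 35,382,649 to 35,382,652, chr9 21,759,945 to 21,759,991, chr15 97,966,026 to 97,966,097, chr11 53,281,723 to 53,281,766, chr4 154,730,573 to 154,730,673 and chr3 107,130,851, with rises down to 64.7 points.

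Regions read in all 17 libraries gave 121 calls of 7259, and 2 of them, chosen after their values were seen, stand for the falls with full coverage of the samples. At chr10 126,457,911 to 126,457,920 the maternal share was 93.2% ± 10.1 (SD, n = 12) at E11.5 and 3.70% ± 3.83 (SD, n = 5) at E17.5 (limma adjusted p = 1.49e-08). At chr14 34,913,458 to 34,913,623 it was 98.9% ± 2.16 (SD, n = 12) and 27.8% ± 11.49 (SD, n = 5, limma adjusted p = 3.80e-09), and this region has a decidua score of 46.8. Without litter B1 the stage calls numbered 104, without E17.5 replicates 3 and 4 they numbered 231 and 203, and with libraries thinned to the same number of sites 2 of 340.

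The yolk sac, the other extraembryonic tissue of the series, showed a balanced autosomal share. It was 52.1% and 52.3% in the 2 yolk sacs against 71.7% ± 10.9 (SD, n = 11) in placentas with mothers of the same strain, a difference of -19.5 points (exact permutation test, p = 0.0256, the smallest possible, adjusted p = 0.0406). On X the yolk sacs were 93.8% and 58.3% maternal, which did not differ from placenta by more than the spread (exact permutation test, p = 0.154, adjusted p = 0.183). The autosomal difference was -2.35 points at sites listed in all 23 placentas, -12.1 without litter C1 and -28.5 without C2, where too few libraries were left for a test. Both yolk sacs listed fewer sites than every placenta of Cast mothers, so tissue and number of sites are confounded.

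Of 33334 regions tested, 694 differed, 596 with a lower and 98 with a higher maternal share in yolk sac (limma, Benjamini-Hochberg), and 22 of the lower regions lay on X. Here all mothers were Cast, so the maternal share is also the Cast share. Parent and strain cannot be told apart in these changes either. The 10 named falls went from 100% in placenta to 0% in both yolk sacs: chrX 160,425,150 (n = 11 placentas, limma adjusted p = 1.56e-08), chr10 29,065,818 to 29,065,973, chr10 32,077,354 to 32,077,603, chrX 89,609,336, chr3 14,013,503 to 14,013,548, chr16 80,971,996 to 80,972,299, chr18 18,457,264 to 18,457,314, chr10 8,903,894 to 8,903,899, chr12 106,004,565 and chr2 93,309,925 to 93,310,013. These falls rested on 7 to 11 placentas, with an SD of 0 in both groups. With the reads per site unknown, their p-values do not measure counting error and do not show a complete switch. The 10 named rises began with chr16 97,790,274 to 97,790,466, from 5.56% ± 17.7 (SD, n = 8) to 100% in both yolk sacs (limma adjusted p = 0.00101). The others were chr5 24,410,046, chr17 29,840,551, chr5 114,813,290 to 114,813,303, chr6 52,994,732, chr11 116,543,217 to 116,543,253, chr1 137,281,647, chr8 87,446,505, chr8 15,033,073 and chr13 6,588,515 to 6,588,773, with rises down to 73.4 points. The region on chromosome 11 is also a paternal locus of the placenta. The spread rests mostly on the placentas, and the count was 4207 without yolk sac replicate 1, 2352 without replicate 2 and 278 without litter C1, of 60920, 62603 and 27854 regions tested.

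The single decidua library has no replicate and no allele share. Its highest score per site was 1010 at chr11 54,723,785 with strands summed, followed by 858 at chr13 61,036,343 and 605 at chr13 61,040,934, and 3 of the 10 highest sites lay within chr7 149,761,615 to 149,761,654. Of its 802382 sites, 84.4% were also listed in a placenta or yolk sac library. Among the autosomal regions read in all 23 placentas, 96 were over 90% maternal in both crosses. Their median decidua score was 5.39, against 0.321 in the 11557 regions with no call.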

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

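The tests of alignment preference, of the regions over 90% maternal and of other splits of the samples were chosen after the result was seen; those of decidua RNA, background reads and number of sites for the maternal excess were written before their result was seen.

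Among the 5 E17.5 placentas, replicate 1 stood apart on X, at 75.9% maternal against 93.7% to 95.0% in the other 4; of 3 measures tested in that group this was the only 1 past the limit, and chance passes it in about 1 group of 20. The excess of X over autosomes was 20.4 points larger at E17.5 than at E11.5 with B6 mothers (37.5 ± 8.98, n = 5, against 17.1 ± 7.39, n = 12, exact permutation test, p = 0.00162, adjusted p = 0.00485 over 6 tests). This restates the autosomal change of -21.5 points, as X changed by -1.08 points. The excess of sites in 10 to 14 placentas over sites in all 23 was -21.7 points at E17.5 relative to E11.5 (3.96 ± 1.403, n = 5, against 25.6 ± 5.59, n = 12, exact permutation test, p = 0.000323, adjusted p = 0.00194). It is the same autosomal fall, from 79.6% to 55.4% at sites of 10 to 14 placentas and from 53.9% to 51.4% at those of all 23.

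As a cause of the maternal excess over the autosomes of E11.5 placentas, alignment preference is argued against by the Cast-mother placentas, whose mean B6 share was 28.3%. Background reads stay open: at sites of 15 or more placentas the lower mean of the crosses was 60.7% maternal, above the bound of 55% set for them, but pooling these sites was a poor choice, since the 60151 sites of 15 to 18 placentas carry that mean (72.0% and 67.2%), while the sites of 19 to 22 were at 56.5% and 54.1% and those of all 23 at 53.9% and 52.2%. The share followed the number of sites (the lower of the tested rho was 0.706), as reads from a source other than the main transcripts may do, and C1, the litter with the largest libraries, was also the most maternal. Decidua RNA cannot be told apart from other causes here: sites of 15 or more placentas with a decidua score of 0.5 or more were less maternal than sites with none (median difference -13.3 points, in 23 of 23 placentas), but that bound was a poor choice, since 6272 of the 6945 high-score sites lie in the class listed in all 23 placentas, and within the class of 15 to 18 placentas the difference was 14.8 points in the other direction (23 of 23), while scores of 0.1 to 0.5 in that class went with lower shares (63.3% and 57.9%, against 72.1% and 69.0% with no signal). Within the class of all 23 placentas the crosses went opposite ways. With B6 mothers scores of 0.5 or more gave 56.1% against 43.4% with no signal, and with Cast mothers 53.3% against 57.9%. Only 208 sites of that class had no signal, and they leaned to the Cast allele in both crosses, so strain enters this contrast. In the class of 19 to 22 placentas the 551 sites with scores of 0.5 or more were at 68.6% and 67.7%, against 54.5% and 58.1% with no signal. Scores of 0.1 to 0.5 in that class gave 57.1% and 52.7%. Without sites of decidua score 0.1 or more the excess was 25.8 and 22.1 points (24.8 and 21.7 with them). This cannot decide the question, since those sites are few and lie mostly in the classes of 19 or more placentas, nearer an even share. Sites of 10 to 14 placentas with no decidua signal were at 79.5% and 74.1% maternal. The 59 sites of that class with a score of 0.5 or more were at 92.7% and 90.035%. As signal missing from 1 decidua library excludes nothing, decidua RNA and an expression bias of the placenta itself stay open as well.

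The autosomal regions over 90% maternal in both crosses and read in all 23 placentas were weighed next. Their decidua score separated them from uncalled regions with an area under the curve of 0.902, which is consistent with RNA from maternal decidua as a source of these regions; over all 1299 maternal regions read in all 23 placentas it was 0.641, and 153 of those had a decidua score under 0.1. In yolk sac the median of the same regions was 47.0% maternal, which argues against a maternal preference that these 2 yolk sacs share. Both are of Cast mothers, so strain is not separated there. Among the 10 strongest of these regions most had a value in only 1 yolk sac, with shares from 0% to 100% and unknown reads per site. Extraembryonic tissue at large is therefore not covered. At E17.5 their median was 98.0% over 91 regions, although the E17.5 autosomes as a whole were near an even share. A placenta-specific maternal expression of genes that the decidua also uses stays open and was not tested.

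Of splits of single placentas, 1 of 100, the real one, gave as many calls between the crosses (82685, highest other 16741), and 1 of 100 between the stages (347, highest other 134). The groups differ in the B6 share of whole libraries: 74.8% against 28.3% between the crosses, and 74.8% at E11.5 against 53.3% at E17.5. Splits that mix the groups can be expected to give fewer calls for that reason alone. The test therefore cannot exclude chance at single regions, and it counts placentas of a litter as independent. The 5 litters allow 10 splits into 3 and 2, too few for a share under 0.05; the real split gave 82685 calls and the highest other, B4 with C1 and C2, gave 37863. The litters of the E17.5 placentas are not named in the labels, and the stage calls fell to 104 without B1, so an effect of litter stays open there too.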

How the results depend on the processing

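No paired analysis was possible because the numbers only name placentas within a litter or group. All alternatives of the shares and those of the region counts other than left-out litters, left-out replicates and litter values (for strain calls these too) were chosen after seeing the data. The alternatives meant for count data (DESeq2, voom, size factors, low-count filters, read duplicates, minimum reads, the list correlation, the fold limits of the decidua set and the removal of its genes) were not run. Depth per site is unknown and limits every region read at few sites. The shares of libraries kept direction and side of the threshold in 51 of the 55 values with a test, and the 8 with too few libraries for a test moved by less than 1 SD; the exceptions concern the difference between the crosses, which turned from 3.15 to -5.79 points without C2 (p = 0.145) and passed at 1.75 points at sites of all 23 placentas, 10.2 without the 6 files of irregular layout and 10.6 without C1. The cause was not tested. Named regions kept direction throughout; 21 of 163 stage values and 25 of 113 yolk sac values lost the threshold, against 0 of 256 for parent of origin.

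Counts of regions moved by over 1.5 times in 49 of 104 values. Parent-of-origin, maternal, paternal and strain calls, in that order, were 227064, 226224, 840 and 28133 with values in at least 3 placentas per cross, 6687, 6546, 141 and 10053 with at least 9, 997, 943, 54 and 4759 with all 23, and 3498, 3430, 68 and 4030 with thinned libraries; fewer or more regions were tested. In windows of 10 kb they were 137373, 137304, 69 and 6443. Relative to the library mean there were 47180 parent-of-origin calls (29988 maternal, 17192 paternal). Without the irregular files, at a lower minimum of Cast-mother placentas, there were 11157 (10901, 256). Paternal calls were 261 with sites joined within 500 bases and 108 when tested in that direction alone. Leaving out litters, at lower minimums of placentas per cross than in the main fit, gave 12240 to 125441 calls, 12021 to 125039 maternal, 219 to 463 paternal and 10761 to 16544 strain calls. Stage calls were 1243 and 163 with values in at least 2 and in all 5 E17.5 placentas, 162 without sites of decidua score 0.1 or more, 576 with strands apart and 2 thinned, and 104 to 302 without a litter or replicate. Yolk sac calls were 341 with at least 9 placentas, 183 thinned, and 278 to 4207 without a litter or replicate. The cause of these shifts was not tested beyond the number of regions.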

Other observations

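The values of X here were looked at after the result was seen and were not tested. In the X interval at 100,650,001 to 100,680,000, 22 of 30 libraries had at least 3 sites. The paternal share of the interval and the maternal share of the rest of X were, per placenta of B6 mothers, 75.2% and 85.7% in B1-2, 85.1% and 76.5% in B1-3, 6.67% and 97.7% in B1-4, 65.9% and 87.1% in B1-5, 0% and 97.2% in B1-6, 71.9% and 91.2% in B3-3, 98.98% and 87.1% in B3-5, 0% and 97.4% in B4-4, and 0% and 96.1% in B4-7. Per placenta of Cast mothers they were 0% and 98.8% in C1-1, 0% and 98.6% in C1-2, 6.25% and 98.8% in C1-3, 70.6% and 89.97% in C1-4, 88.6% and 82.3% in C1-5, 85.9% and 79.97% in C2-1, 0% and 95.8% in C2-2, 85.5% and 74.9% in C2-3, 0% and 96.9% in C2-4, 85.9% and 84.0% in C2-5, and 0% and 97.8% in C2-6. E17.5 replicate 1 had 100% and 76.4%, and yolk sac replicate 2 had 84.8% and 58.4%. The values fall into separate clusters in both crosses, so no correlation is given, and the sex of the conceptuses is not in the labels.

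Of the paternal regions of E11.5, 61 entered the stage test and 0 passed it by limma, with 2 at an unadjusted p under 0.05 (median difference -3.86 points), while 64 entered the yolk sac test, where 4 passed and 15 had an unadjusted p under 0.05 (median difference 1.03 points). Among the paternal loci with several regions, the mean maternal share in yolk sac was 57.6% at chr2 174,092,089 to 174,092,797 (2 regions) and 100% at chr8 125,390,743 to 125,391,181 (1 region with a value), where the E17.5 placentas had 1.24% and 0%.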
